A study of Xenopus tropicalis with 12 samples.

How the data were processed

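The authors deposited RSEM expected counts for 33875 gene models in 12 libraries, as a combined matrix and as a table per library. The tables per library also hold TPM and effective lengths as deposited, per the file headers. The submitters' processing notes name CASAVA 1.8.2, cutadapt, Bowtie, RSEM and DESeq2 without giving the part each played. The genome build and the gene annotation are not given in the sources used here, so no coordinates are printed. Per the labels, each of the 4 stages had 3 biological replicates, and the number of animals behind a sample is not given in the sources used here. The matrix and the tables per library held the same expected counts. The tables per library hold 35241 lines, because a model repeats where it has several annotated genes, and each model was taken a single time.

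Gene names came from the annotation column of the deposited files. The RefSeq gene table of assembly UCB_Xtro_10.0, used for names only, named a further 160 annotation entries. In all 13301 models had a name and 20574 had none; 400 models carried more than 1 name and count reads of either gene, and 693 names sat on more than 1 model. The genes dio2, tet3 and crh matched no named model and were not analysed here.

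Of the expected counts, 53.7% were not whole numbers, since RSEM divides reads among models; they were rounded to the nearest whole number. Models were kept by edgeR's filterByExpr by stage (minimum count 10, minimum total 15), which left 19584 models with 99.93% of the counts, 11562 of them named. Libraries were scaled by TMM factors. A quasi-likelihood model with a mean per stage was fitted to all 12 libraries in edgeR 4.0.16 (R 4.3.3), and each contrast was tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The biological coefficient of variation was 18.3%. Contrasts were NF56 against NF50, NF62 against NF56, NF66 against NF62, NF66 against NF50, and NF62 against the mean of NF56 and NF66; a further test asked for any difference among stages. Principal components, the within-stage axis (the leading component of the residuals after the stage means) and list levels used log2 CPM with a prior count of 2. Effective lengths of a model differed by at most 0.01 between libraries.

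In total 26 gene lists were written before the data were examined, as were the contrasts, the tests, the rule for named genes and the alternatives, except where the text says otherwise. They cover thyroid hormone signalling machinery, thyroid hormone response genes of tadpole tissues, DNA methylation, Polycomb and histone methylation enzymes, DNA replication and cell division, neural progenitors, neurogenesis, oligodendrocytes, synapses, hypothalamic neuropeptides, microglia, red blood cells, vascular cells, choroid plexus, pituitary, retina and pineal, skeletal muscle, glucocorticoid receptors and response genes, cholesterol synthesis, apoptosis, axon guidance, extracellular matrix proteases, immediate early genes, heat shock, oxidative phosphorylation and ribosomal proteins. Of their 941 symbols, 779 matched a named model. Lists with at least 5 tested members were compared with all other genes by camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 104 tests of 26 lists in 4 contrasts. Camera called 47 of these tests, and 9 of the 47 held with an estimated correlation. In 99 regroupings of the libraries across stages, camera with the preset correlation called a median of 28 of the 104 tests. The regrouped libraries keep their stage differences, so this is not a rate in the absence of differences. A call with the preset correlation alone is still taken as a weak statement about the stages, since few held with an estimated correlation. By fry, which asks whether the members move on balance in 1 direction without comparing them with other genes, 46 of the 47 were also called. Median, mean and test of a list differed in sign only where the list was not called. This was the case at NF56 against NF50 for myelin, apoptosis and matrix proteases, at NF62 against NF56 for vascular cells and axon guidance, at NF66 against NF62 for synapses and skeletal muscle, and at NF66 against NF50 for glucocorticoid response genes and matrix proteases.

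The named genes follow a rule. Key genes of thyroid hormone action, DNA methylation, division and myelin are reported whatever their values. For each pair of successive stages, each list that was called, or that had at least 3 members past the threshold, gives the 2 members with the largest absolute log2 fold change among those past the threshold with an average log2 CPM of at least 1. Each contrast gives the 5 largest rises and 5 largest falls among genes past the threshold whose libraries did not overlap between the groups, with at least 5 CPM in the higher group and a gene symbol. Some genes that the rule names are not reported here. Of the values the rule gives, 171 were past the threshold.

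As a self-test, counts with known changes were simulated with the depths and dispersions of these libraries. For NF62 against NF56, edgeR recovered 53.1% of 2-fold and 85.6% of 4-fold changes and called 6 of 19153 unchanged genes. A list of 40 genes that were all raised in the simulation gave a camera p of 3.7e-85 and an unchanged list 0.96. Genes were simulated independently, so the self-test does not cover lists with correlated members or the within-stage axis.

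Alternatives were median-of-ratios factors, DESeq2 1.42.0, no low-count filter or a stricter filter (1 CPM), the replicate number as a block, a test against a minimum fold change of 1.5, effective lengths as offsets, limma on log2(TPM + 1), a fit to only the libraries of the stages compared, a prior count of 0.5 or the 500 most variable genes for the components, an estimated correlation or fry for the lists, and each library left out in turn. Text handling and figures used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.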

Results

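RNA was sequenced from the middle part of the brain of wild-type Xenopus tropicalis, a region that holds the preoptic area, the hypothalamus and the thalamus. Animals were taken at 4 Nieuwkoop-Faber (NF) stages of metamorphosis. NF50 is premetamorphosis, NF56 prometamorphosis, NF62 the climax, when circulating thyroid hormone is high, and NF66 the end of metamorphosis. Each stage had 3 libraries, numbered 1, 3 and 4 at NF50 and 1, 2 and 3 at the other stages, which the labels call biological replicates. The total expected count per library ranged from 12046529 (NF56 replicate 3) to 31029733 (NF66 replicate 3), and the other libraries held 19732166 to 25551912. Values per gene are read counts normalised to library size (CPM), as mean ± SD with n = 3 libraries per stage. Fold changes are on the log2 scale with their standard error (SE), from edgeR's quasi-likelihood fit to all 12 libraries. A gene is said to have risen, fallen or changed only where its Benjamini-Hochberg adjusted p was below 0.05 over the 19584 gene models tested.

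The leading principal component held 38.7% of the variance of the log2-CPM values and set the NF50 libraries (-72 to -39.9) apart from the others. The other stages overlapped along it, NF56 at -23.2 to 17.3, NF62 at 2.9 to 46.3 and NF66 at 11.2 to 57.9. The next component held 27.2%, and both components spread the libraries within stages. A single axis held 54.2% of the variance left within stages, with NF62 replicate 2 at its lowest position (-54.2) and NF66 replicate 3 at its highest (49.8). Spearman correlations between libraries had a median of 0.987 with a range of 0.975 to 0.995 within stages, and a median of 0.976 with a range of 0.947 to 0.993 between stages, so the ranges overlapped.

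**Figure D1:**
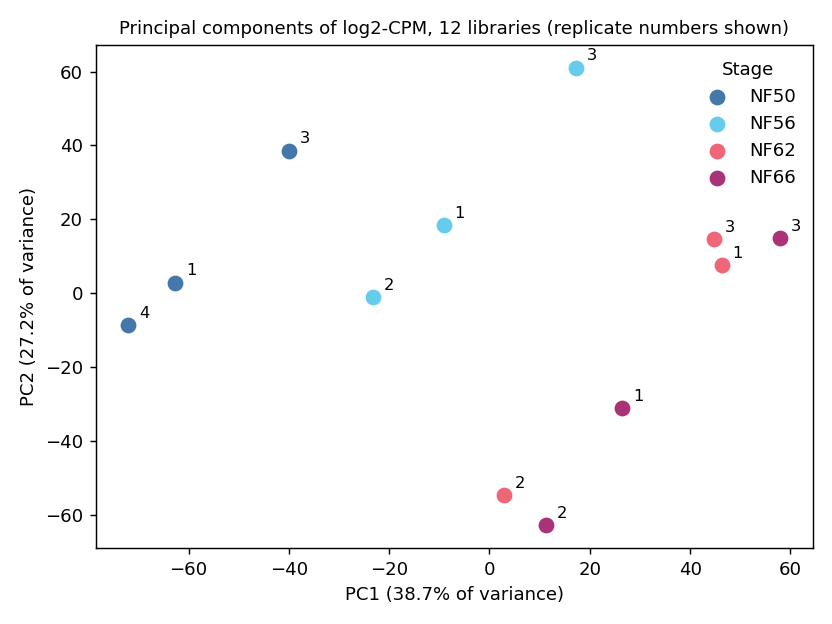
Position of each of the 12 libraries on the leading pair of principal components of the log2-CPM values, coloured by stage, with the percentage of variance on each axis. The NF50 libraries stand apart on the leading component (-72 to -39.9), the libraries of the other stages overlap on it (-23.2 to 57.9), and libraries of a stage spread along both.

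The comparison of NF56 with NF50 asks what changes as the thyroid begins to release hormone, before the climax. At NF56, 1275 genes were higher and 1559 lower than at NF50 (14.5% of those tested), and 118 and 368 of these differed by at least 2-fold. By limma on log2(TPM + 1) without a scaling factor, 333 were higher and 122 lower, and the median log2 fold change of all genes tested was 0.32 in place of -0.002. Falls of lists and genes at NF56 are therefore relative to the other genes. On that unscaled measure the medians of the lists of oxidative phosphorylation (0.10 in place of -0.27), heat shock and the unfolded protein response (0.17 in place of -0.21), choroid plexus and ependyma (0.09 in place of -0.27) and vascular and meningeal cells (0.02 in place of -0.32) changed sign. Without NF50 replicate 1 the counts were 694 higher and 916 lower, and without NF56 replicate 1 they were 716 and 893. Leaving out NF50 replicate 4 gave 641 higher, and leaving out NF56 replicate 3 gave 834 higher and 981 lower.

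Among genes of thyroid hormone action, klf9, a transcription factor gene that the hormone receptors bind and induce directly, rose from 6.11 ± 0.898 to 26.5 ± 5.6 CPM (n = 3), a log2 fold change of 2.10 ± 0.33 (adjusted p = 0.0024). The receptor gene thrb, itself induced by the hormone in tadpoles, rose from 9.7 ± 1.33 to 18.3 ± 1.15 CPM (0.91 ± 0.15). The cytosolic hormone-binding protein gene crym rose (1.35 ± 0.13), and slc7a5, which codes for a transporter of large neutral amino acids and thyroid hormones, fell (-1.4 ± 0.25). The slc7a5 level was 284.3, 538.6 and 222.8 CPM in NF50 replicates 1, 3 and 4. With 1 library left out its log2 fold change was -1.64 to -0.96. The gene dio3, whose deiodinase inactivates the hormone, was at 2.73 ± 0.591 and 3.36 ± 0.328 CPM (0.28 ± 0.19, adjusted p = 0.35). A model that carries the name of the other receptor, thra, was on average below 1 CPM at every stage, with a log2 fold change of 0.23 ± 0.39. Whether that model covers the main locus of the receptor was not analysed here, so its level is not read as that of the gene. Of the 17 thyroid hormone response genes of tadpole tissues that were tested, 4 rose, 3 fell and 10 passed in neither direction; adjusted over the list alone, 4 rose and 5 fell (camera adjusted p = 0.326). Of the 22 genes of thyroid hormone signalling machinery, 3 rose, 3 fell and 16 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.549).

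Genes of DNA methylation changed individually, and the list as a whole was not called (1 of 20 higher, 4 lower and 15 not passing; adjusted over the list alone 3 and 4; camera adjusted p = 0.375). The de novo methyltransferase gene dnmt3a rose from 371 ± 4.35 to 510 ± 34.4 CPM (0.46 ± 0.06, adjusted p = 0.00083). The gene uhrf1, whose product brings the maintenance methyltransferase to newly replicated DNA, fell from 41.8 ± 3.28 to 13.6 ± 1.55 CPM (-1.62 ± 0.15, adjusted p = 0.0002). The stress gene gadd45g, which has been linked to demethylation, fell from 36.3 ± 3.49 to 20.8 ± 1.54 CPM (-0.80 ± 0.16). Of the others, dnmt1 stood at 67 ± 1.95 and 61.4 ± 5.93 CPM (-0.13 ± 0.07) and tet2 at 76.8 ± 2.35 and 84.4 ± 5.67 (0.14 ± 0.06), and neither passed. Of the 33 Polycomb and histone methylation enzymes, 0 rose and 2 fell by edgeR, also adjusted over the list alone (camera adjusted p = 0.765).

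Cell division genes fell in number. Of 67 genes of DNA replication and cell division, 53 fell, 1 rose and 13 did not pass, with a median log2 fold change of -1.07; adjusted over the list alone, 58 fell and 1 rose. The camera adjusted p was 6.59e-33 (adjusted p = 0.000972 with an estimated correlation). Examples are the condensin gene smc2, which fell from 20.1 ± 0.938 to 5.57 ± 0.64 CPM (-1.85 ± 0.15), and the mitotic kinesin gene kif23, from 21 ± 2.39 to 5.9 ± 0.597 CPM (-1.83 ± 0.14). The replication clamp gene pcna, in a gene model merged with figla, fell from 88.7 ± 7.13 to 39.6 ± 0.414 CPM (-1.16 ± 0.08), so its reads are of either gene. Of 30 genes of neural progenitors and radial glia, 15 fell and 0 rose, and adjusted over the list alone 18 fell (median -0.45; camera adjusted p = 5.48e-10, and 0.0318 with an estimated correlation). The Notch-responsive repressor gene hes3.3 fell from 11.5 ± 0.736 to 3.89 ± 0.589 CPM (-1.56 ± 0.17), and the glutamine synthetase gene glul from 242 ± 63.3 to 104 ± 15.2 CPM (-1.22 ± 0.34). Genes of neurogenesis and immature neurons moved little as a list (2 of 33 higher, 3 lower, also adjusted over the list alone; camera adjusted p = 0.48), although the Notch ligand gene dll1 fell from 53.4 ± 2.49 to 30.9 ± 1.15 CPM (-0.79 ± 0.09).

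Of 70 cytosolic ribosomal protein genes, 69 fell and 0 rose, with a median log2 fold change of -0.79; adjusted over the list alone all 70 fell. The list was called with the preset correlation (camera adjusted p = 4.82e-30) and lost with an estimated correlation (adjusted p = 0.251 with an estimated correlation). The gene rps12 fell from 2090 ± 316 to 992 ± 169 CPM (-1.07 ± 0.19) and rpl23 from 1080 ± 196 to 561 ± 94.6 CPM (-0.95 ± 0.24). Of 45 nuclear-encoded genes of oxidative phosphorylation, 19 fell and 0 rose, and 29 fell adjusted over the list alone (median -0.27; camera adjusted p = 5.6e-11). That call was lost (adjusted p = 0.127 with an estimated correlation). The cytochrome c gene cycs fell from 78.4 ± 2.56 to 41.1 ± 4.65 CPM (-0.93 ± 0.09). Of 29 genes of heat shock and the unfolded protein response, 11 fell and 2 rose, or 15 and 4 adjusted over the list alone (median -0.21; camera adjusted p = 0.00655; adjusted p = 0.263 with an estimated correlation). The asparagine synthetase gene asns fell from 50.3 ± 26.1 to 14.1 ± 1.42 CPM (-1.83 ± 0.28), and chac1, which codes for a glutathione-degrading enzyme, from 11.5 ± 10.7 to 1.54 ± 0.866 CPM (-2.88 ± 0.86).

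Of 55 genes of synapses and mature neurons, 9 rose and 1 fell, or 12 and 4 adjusted over the list alone (median 0.15; camera adjusted p = 0.0201; adjusted p = 0.21 with an estimated correlation); without NF56 replicate 3 the list's adjusted p was 0.0588. The receptor subunit gene gabra3 rose from 184 ± 12.6 to 284 ± 12.7 CPM (0.63 ± 0.07) and the calcium-binding protein gene calb1 from 28.8 ± 0.68 to 40.9 ± 1.34 CPM (0.51 ± 0.10). Of 42 axon guidance genes, 10 rose and 5 fell, or 13 and 5 adjusted over the list alone (median 0.12; camera adjusted p = 0.0362; adjusted p = 0.509 with an estimated correlation). That list was not called without NF50 replicate 4 or without NF56 replicate 3, and its adjusted p reached 0.202. The netrin gene ntn1 fell from 31.8 ± 2.84 to 17.2 ± 1.42 CPM (-0.89 ± 0.14). Hypothalamic neuropeptide and transmitter genes were not called as a list (1 of 30 higher and 7 lower, or 2 and 7 adjusted over the list alone; camera adjusted p = 0.0577). Among them avp, which codes for the precursor of vasotocin, rose from 22.3 ± 3.79 to 49.6 ± 5.81 CPM (1.16 ± 0.24), cartpt fell (-0.91 ± 0.20), and pomc was at 84.9 ± 16.5 and 64.3 ± 2.69 CPM (-0.40 ± 0.31, adjusted p = 0.42). The myelin gene mbp was at 519 ± 29.3 and 555 ± 10 CPM (0.10 ± 0.08), and of 24 genes of oligodendrocytes and myelin 1 rose and 1 fell, also adjusted over the list alone.

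Markers of other cell types moved as follows. Of 12 red blood cell genes, 4 fell and 0 rose, or 5 fell adjusted over the list alone (camera adjusted p = 0.00116; adjusted p = 0.113 with an estimated correlation). Of 27 vascular and meningeal genes, 6 fell and 2 rose, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.00408; adjusted p = 0.127 with an estimated correlation). The endothelial cadherin gene cdh5 fell from 5.17 ± 0.298 to 2.57 ± 0.298 CPM (-1.01 ± 0.16). Of 17 genes of the choroid plexus and ependyma, 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0112; adjusted p = 0.17 with an estimated correlation). Among them were msx1 (-1.45 ± 0.31) and otx2 (-0.56 ± 0.08). The choroid plexus list was not called with the replicate number as a block (camera adjusted p = 0.0656). Of 25 genes of microglia and leukocytes, 5 rose and 0 fell, or 7 rose adjusted over the list alone (camera adjusted p = 0.107). Among them were the antigen presentation gene cd74, which rose from 17 ± 0.658 to 49.3 ± 1.18 CPM (1.53 ± 0.30), and the lysosomal gene cd68 (0.77 ± 0.13). Of 19 skeletal muscle genes, 2 rose and 4 fell, or 2 and 6 adjusted over the list alone (camera adjusted p = 0.107). The calcium channel gene ryr1 rose from 8.99 ± 0.645 to 19.6 ± 2.57 CPM (1.12 ± 0.11). Retina and pineal genes (1 of 18 higher and 3 lower, or 1 and 4 adjusted over the list alone) and pituitary genes (0 of 16 higher and 1 lower, also adjusted over the list alone) were not called, with camera adjusted p of 0.0988 and 0.253.

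Among genes with a symbol, libraries that did not overlap and at least 5 CPM in the higher group, the largest falls at NF56 were those of the receptor gene eda2r (-3.42 ± 0.51), the elongation factor gene eef1a1o (-2.21 ± 0.21), the condensin gene ncaph2 (-2.15 ± 0.20), the replication helicase gene cdc45 (-2.03 ± 0.23) and the small nucleolar RNA gene snord89 (-2.02 ± 0.21). After klf9, the largest rises within those limits were those of uts2rl3 (1.60 ± 0.37), cd74, the transcription factor gene nfix (1.41 ± 0.12) and the transporter gene slco4a1 (1.38 ± 0.18). Without NF50 replicate 3 the log2 fold change of eda2r was -2.65. With 1 library left out, chac1 lost its call in 11 of 12 fits (log2 fold change -3.46 to -2.0) and glul in 8 (-1.35 to -1.0). The gene rpl23 lost its call without NF50 replicate 1 or 4 or NF56 replicate 1 or 3 (-1.11 to -0.84). The calls of uts2rl3 (1.49 to 1.68; NF50 replicates 1 and 4, NF56 replicate 1), cartpt (-1.0 to -0.83; NF50 replicate 1, NF56 replicates 1 and 3) and msx1 (-1.59 to -1.35; NF56 replicate 1) were also lost without those libraries. A model that carries the name tmed2 had 0 counts in the NF50 libraries and stood at 12.42, 3.06 and 0 CPM in NF56 replicates 1, 2 and 3.

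Smaller changes of list members at NF56 were those of the sterol reductase gene lbr (-0.84 ± 0.10) and of the merged models cebpd/rps20 (-0.89 ± 0.18) and rpl17/atp5a1 (-0.73 ± 0.16). Further falls were those of the photoreceptor and pigment epithelium genes pde6g (-0.88 ± 0.26) and rlbp1 (-0.84 ± 0.22), the smooth muscle gene tagln (-0.86 ± 0.21), the heme synthesis gene hmbs (-0.71 ± 0.19) and the merged globin model hbd/hbg2 (-0.64 ± 0.16). Rises were those of dpysl5 (0.65 ± 0.15), adamts9 (0.65 ± 0.16), mmp11 (0.63 ± 0.17), hmgcs1 (0.54 ± 0.16), bmf (0.46 ± 0.13) and the merged model casq1/scnm1 (0.43 ± 0.12). Each of these falls and rises from pde6g to casq1/scnm1 lost its call in 3 to 9 of the 12 fits with 1 library left out, in every case including the fit without NF50 replicate 1. Of 30 extracellular matrix proteases and inhibitors, 7 rose and 1 fell, or 8 and 4 adjusted over the list alone (median 0.02, mean -0.04; camera adjusted p = 0.291), and of 22 apoptosis genes 1 rose and 2 fell, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.913).

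The comparison of NF62 with NF56 asks what changes as the animals reach the climax of metamorphosis. At NF62, 1947 genes were higher and 1757 lower than at NF56 (18.9% of those tested), and 210 and 326 differed by at least 2-fold. By limma on log2(TPM + 1), 173 were higher and 274 lower. Without NF62 replicate 1, 1108 genes were lower.

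Of the 17 thyroid hormone response genes, 9 rose, 1 fell and 7 did not pass, or 10 and 3 adjusted over the list alone, with a median log2 fold change of 0.40 (camera adjusted p = 0.000372, and 0.0318 with an estimated correlation). The hormone-induced transcription factor gene thibz rose from 0.763 ± 0.521 to 52.5 ± 5.87 CPM (6.04 ± 0.45, adjusted p = 2e-05). The deiodinase gene dio3 rose from 3.36 ± 0.328 to 58.6 ± 2.17 CPM (4.13 ± 0.18, adjusted p = 8.5e-07). The gene klf9 reached 136 ± 43 CPM (2.37 ± 0.31) and thrb 75.8 ± 11 CPM (2.05 ± 0.15). Of the 22 genes of thyroid hormone signalling machinery, 5 rose and 1 fell, also adjusted over the list alone (median 0.04, and -0.01 on log2(TPM + 1); camera adjusted p = 0.0437; adjusted p = 0.277 with an estimated correlation). That list was not called without NF50 replicate 3, NF56 replicate 1 or 2, NF62 replicate 1 or 3, or NF66 replicate 1, where its adjusted p reached 0.0924. Nor was it called with the stricter filter, with the replicate number as a block, or with only the libraries of the stages compared. The thra model had a log2 fold change of -0.19 ± 0.39, which did not pass. Among 20 glucocorticoid receptors and response genes, 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.517). The mineralocorticoid receptor gene nr3c2 rose from 16.6 ± 2.69 to 42 ± 3.06 CPM (1.34 ± 0.14). At NF56 against NF50 the counts for that list were 2 and 3, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.14).

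**Figure D2:**
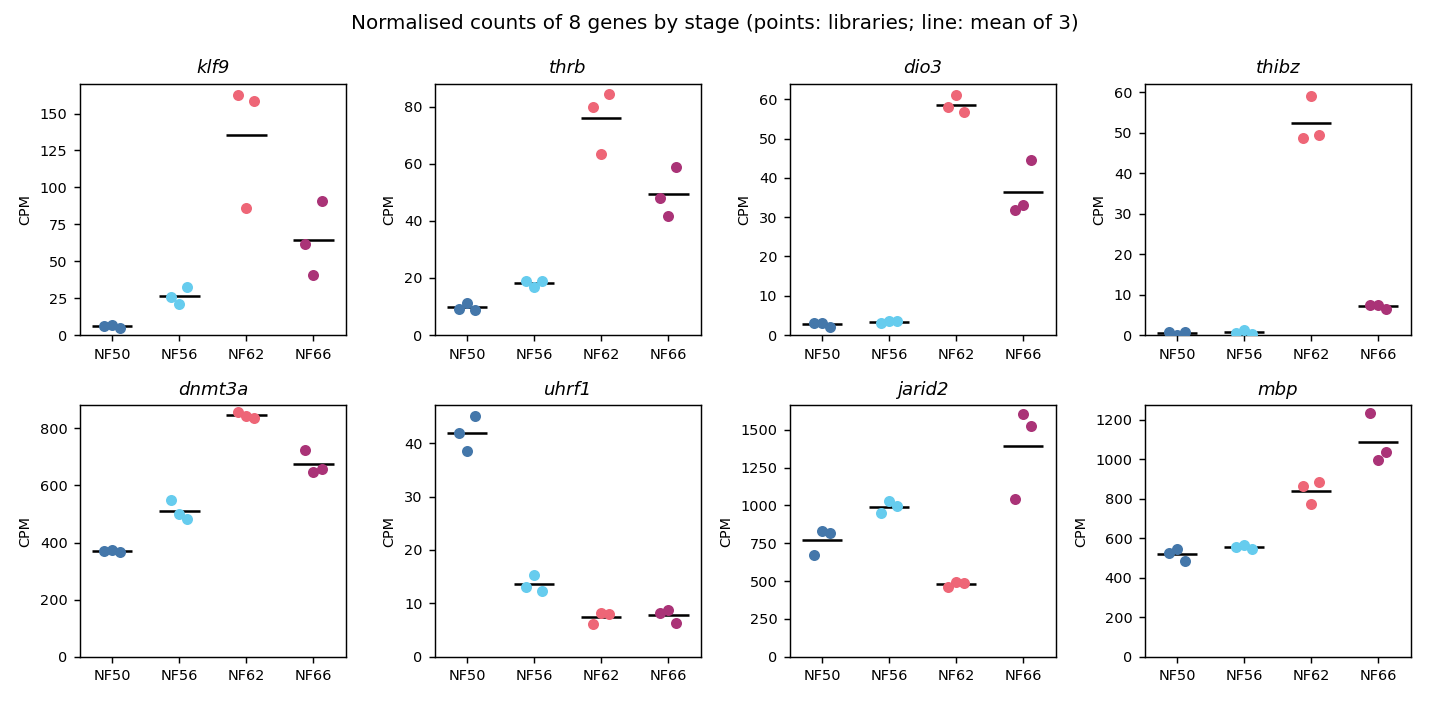
CPM (linear axis) of klf9, thrb, dio3, thibz, dnmt3a, uhrf1, jarid2 and mbp in each of the 12 libraries by stage. The genes thibz and dio3 rise at NF62 to 52.5 and 58.6 CPM on average, and jarid2 is lowest there (482 CPM).

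The methyltransferase gene dnmt3a rose further, to 845 ± 9.8 CPM (0.73 ± 0.06, adjusted p = 3.5e-05). The maintenance genes fell, dnmt1 to 43 ± 2.06 CPM (-0.51 ± 0.07) and uhrf1 to 7.47 ± 1.12 CPM (-0.87 ± 0.15). The values of tet2 (80.8 ± 2.53 CPM, -0.06 ± 0.06) and gadd45g (21.6 ± 3.21 CPM, 0.06 ± 0.16) did not pass. The DNA methylation list had 1 rise and 4 falls among 20, or 1 and 5 adjusted over the list alone (camera adjusted p = 0.0813). Of 33 Polycomb and histone methylation enzymes, 3 rose and 9 fell, or 3 and 10 adjusted over the list alone (camera adjusted p = 0.0797). The Polycomb cofactor gene jarid2 fell from 993 ± 39.3 to 482 ± 17.9 CPM (-1.04 ± 0.14), and cbx2, which codes for a reader of Polycomb-marked histones, fell from 39.7 ± 3.69 to 25.3 ± 2 CPM (-0.65 ± 0.09).

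Of 67 replication and cell division genes, 37 fell and 1 rose, or 41 and 3 adjusted over the list alone (median -0.54; camera adjusted p = 2.21e-16, and 0.00489 with an estimated correlation). Among them were the spindle genes nusap1 (10.8 ± 0.417 to 2.62 ± 0.401 CPM, -2.05 ± 0.13) and cdca8 (-1.91 ± 0.33). The merged pcna/figla model was at 34.2 ± 1.4 CPM (-0.21 ± 0.08, adjusted p = 0.081). Of 30 progenitor and radial glia genes, 13 fell and 2 rose, or 14 and 2 adjusted over the list alone (median -0.26; camera adjusted p = 1.21e-05; adjusted p = 0.113 with an estimated correlation). The intermediate filament gene nes fell from 53.9 ± 7.3 to 11.5 ± 2.69 CPM (-2.23 ± 0.30) and the Notch target gene hes5.1 from 24.8 ± 0.664 to 8.4 ± 1.26 CPM (-1.56 ± 0.12). Of 33 genes of neurogenesis and immature neurons, 16 fell and 2 rose, or 17 and 3 adjusted over the list alone (median -0.55; camera adjusted p = 2.91e-05; adjusted p = 0.124 with an estimated correlation). The Notch ligand gene dll1 fell to 14.4 ± 2.04 CPM (-1.10 ± 0.09), and the model that merges sox4 with u4 fell (-1.03 ± 0.11).

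Of 55 genes of synapses and mature neurons, 27 rose and 1 fell, also adjusted over the list alone, with a median of 0.28 (camera adjusted p = 8.46e-09, and 0.0243 with an estimated correlation). The neurofilament gene nefl rose from 192 ± 6.27 to 351 ± 51.7 CPM (0.87 ± 0.13) and the complexin gene cplx1 from 880 ± 19.1 to 1550 ± 13 CPM (0.81 ± 0.05). Of 30 neuropeptide and transmitter genes, 11 rose and 1 fell, or 11 and 2 adjusted over the list alone (median 0.27; camera adjusted p = 0.000167; adjusted p = 0.127 with an estimated correlation). The vasotocin gene avp rose to 146 ± 27.2 CPM (1.56 ± 0.23) and the cholecystokinin gene cck from 18 ± 1.26 to 33.3 ± 2.89 CPM (0.89 ± 0.08), while pomc was at 54.1 ± 8.26 CPM (-0.25 ± 0.31). Of 24 genes of oligodendrocytes and myelin, 10 rose and 1 fell, or 10 and 3 adjusted over the list alone (median 0.33; camera adjusted p = 0.0529). The myelin genes mbp (555 ± 10 to 840 ± 58.8 CPM, 0.60 ± 0.08) and mag (0.92 ± 0.21) rose, and enpp6, a marker of newly formed oligodendrocytes, fell from 4.31 ± 0.567 to 2.29 ± 0.542 CPM (-0.91 ± 0.19). Axon guidance genes were not called (5 of 42 higher and 4 lower, or 6 and 5 adjusted over the list alone; camera adjusted p = 0.674), and within the list ntn3 (-1.12 ± 0.21) and efna2 (-0.73 ± 0.06) fell.

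Of 70 ribosomal protein genes, 40 fell and 0 rose, and 63 fell adjusted over the list alone (median -0.53; camera adjusted p = 2.39e-17; adjusted p = 0.348 with an estimated correlation). The gene rpl3 fell from 1570 ± 96.3 to 930 ± 84.1 CPM (-0.76 ± 0.09) and rpl11 from 715 ± 88.7 to 430 ± 67 CPM (-0.73 ± 0.15). Of 45 oxidative phosphorylation genes, 12 rose and 2 fell, or 15 and 4 adjusted over the list alone (median 0.14; camera adjusted p = 0.00282; adjusted p = 0.387 with an estimated correlation), and cycs rose to 68 ± 4.09 CPM (0.72 ± 0.09). Of 29 heat shock and unfolded protein response genes, 12 rose and 2 fell, or 14 and 3 adjusted over the list alone (median 0.23; camera adjusted p = 0.00527; adjusted p = 0.256 with an estimated correlation). Among them was manf, which codes for a secreted protein of the endoplasmic reticulum stress response (0.81 ± 0.19). The heat shock list was not called by DESeq2. The oxidative phosphorylation list was not called with NF56 replicate 3 and NF62 replicate 2 removed together. Of 30 extracellular matrix proteases and inhibitors, 11 rose and 2 fell, also adjusted over the list alone (median 0.17; camera adjusted p = 0.00527; adjusted p = 0.241 with an estimated correlation). Among them were the aggrecanase genes adamts5 (56.7 ± 4.53 to 110 ± 3.08 CPM, 0.96 ± 0.07) and adamts4 (0.89 ± 0.17). Of 25 microglia and leukocyte genes, 4 fell and 0 rose, also adjusted over the list alone (median -0.47; camera adjusted p = 0.000448; adjusted p = 0.0812 with an estimated correlation). The growth factor receptor gene csf1r, on which microglia depend, fell from 14.7 ± 1.41 to 9.5 ± 0.801 CPM (-0.63 ± 0.11).

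Other lists were not called. Of 12 red blood cell genes, 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.0924); the merged globin model hbd/hbg2 fell from 503 ± 56.1 to 141 ± 17.1 CPM (-1.83 ± 0.16). Retina and pineal genes had 3 rises and 2 falls among 18, also adjusted over the list alone (camera adjusted p = 0.347); prph2 rose (1.19 ± 0.16) and guca1b fell (-0.81 ± 0.17), both photoreceptor genes. Pituitary genes had 4 rises and 2 falls among 16, or 5 and 2 adjusted over the list alone (camera adjusted p = 0.253). The growth hormone gene gh1 fell from 36 ± 1.28 to 15.8 ± 5.49 CPM (-1.19 ± 0.28), a call lost without NF62 replicate 1 (adjusted p = 0.0542). The prolactin gene prl rose from 2.93 ± 1.11 to 7.58 ± 3.04 CPM (1.4 ± 0.40), a call lost without NF56 replicate 1 or 2 or NF62 replicate 1 or 3 (adjusted p up to 0.119). Apoptosis genes had 2 rises and 3 falls among 22, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.508), and cholesterol synthesis genes 1 and 2 among 18, or 2 and 2 adjusted over the list alone (camera adjusted p = 0.937). Of 26 immediate early genes, 2 rose and 0 fell, also adjusted over the list alone (camera adjusted p = 0.204).

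Among genes with a symbol, libraries that did not overlap and at least 5 CPM in the higher group, the largest falls were those of crisp1.7, which codes for a cysteine-rich secreted protein (6.74 ± 2.66 to 0.167 ± 0.117 CPM, -5.33 ± 0.52), the secreted phospholipase gene pla2g2e (-3.85 ± 0.34), the zinc finger gene znf704 (-3.49 ± 0.26), nes and nusap1. After thibz and dio3, other large rises were those of lman1l (2.47 ± 0.60) and the activin subunit gene inhbb (1.59 ± 0.367 to 8.48 ± 1.39 CPM, 2.44 ± 0.30). Without NF62 replicate 3 the value of crisp1.7 was -6.01, and without NF56 replicate 2 that of thibz was 6.75. The call of lman1l was lost without NF56 replicate 1 or 2 or NF62 replicate 1 (2.12 to 3.33).

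Further list members that changed at NF62 were the merged model ddx21/cox5b.2 (-0.98 ± 0.07), the roof plate gene lmx1a (-0.92 ± 0.17) and the sterol carrier gene stard4 (0.69 ± 0.10). Falls of the merged globin model hba3/hba4 (-0.94 ± 0.25), the smooth muscle actin gene acta2 (-0.83 ± 0.23), fli1 (-0.69 ± 0.16), spag6 (-0.63 ± 0.18), lbr (-0.41 ± 0.10) and the merged model acta1/sf3b5 (-0.20 ± 0.06) lost their calls in 1 to 7 of the 12 fits with 1 library left out. The rises of the heat shock gene hspa1b (0.95 ± 0.25) and of ryr1 (0.37 ± 0.11) did so in 4 and 6. In every case the fit without NF62 replicate 1 was among them. Of 27 vascular and meningeal genes, 2 rose and 3 fell, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.888). Of 17 choroid plexus and ependyma genes 3 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 0.249), and of 19 skeletal muscle genes 1 rose and 4 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.0988).

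The comparison of NF66 with NF62 asks which levels change as metamorphosis ends. At NF66, 270 genes were higher and 350 lower than at NF62 (3.2% of those tested), 31 and 28 of them by at least 2-fold, and 3207 had an unadjusted p below 0.05. Counts here depended on single libraries. Higher and lower genes numbered 38 and 75 without NF62 replicate 3, 74 and 112 without NF62 replicate 1, 76 and 82 without NF66 replicate 2, and 164 and 150 without NF62 replicate 2. They numbered 145 and 195 without NF50 replicate 1, 162 and 229 without NF56 replicate 1, 174 and 230 without NF56 replicate 2, and 167 and 184 without NF66 replicate 1. Without NF50 replicate 4, 216 genes were lower. By limma on log2(TPM + 1), 1 was higher and 2 lower, and by DESeq2 623 and 743. With only the libraries of NF62 and NF66 in the fit, edgeR called 0 higher and 4 lower, with 2415 genes at an unadjusted p below 0.05. A regrouping of those 6 libraries that follows the within-stage axis called 2165 genes, more than the stages did.

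Of the 17 thyroid hormone response genes, 6 fell and 0 rose, or 9 fell and 1 rose adjusted over the list alone (median -0.32; camera adjusted p = 2.57e-05, and 0.0243 with an estimated correlation). The gene thibz fell from 52.5 ± 5.87 to 7.08 ± 0.598 CPM (-2.89 ± 0.36, adjusted p = 0.0039). The matrix protease gene mmp11, a response gene of resorbing tadpole tissues, fell from 11.4 ± 0.401 to 4.92 ± 0.403 CPM (-1.22 ± 0.16). The level of klf9 was 64.5 ± 25.1 CPM at NF66 (-1.07 ± 0.30, adjusted p = 0.084). Of the 22 signalling machinery genes, 6 fell and 0 rose, also adjusted over the list alone (median -0.11, camera adjusted p = 0.00622, and 0.2 with an estimated correlation). The median of that list was -0.238 to -0.055 with 1 library left out. The gene dio3 fell to 36.4 ± 7.07 CPM (-0.68 ± 0.15) and thrb to 49.5 ± 8.57 CPM (-0.61 ± 0.14), but these calls were lost in 8 and 10 of the 12 fits with 1 library left out, where the log2 fold changes were -0.86 to -0.59 and -0.76 to -0.51. The fall of crym (-0.69 ± 0.13) was not called without NF62 replicate 1 or 2 or NF66 replicate 1 or 2 (-0.79 to -0.64). The thra model was at 0.809 ± 0.117 CPM (0.18 ± 0.38).

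Of 18 genes of cholesterol synthesis, 11 fell and 0 rose, with a median log2 fold change of -0.62, and 16 fell adjusted over the list alone. The list was called with the preset correlation (camera adjusted p = 6.17e-17) and lost with an estimated correlation (adjusted p = 0.113 with an estimated correlation). The synthase gene hmgcs1 fell from 436 ± 37.6 to 188 ± 38.6 CPM (-1.21 ± 0.16) and the thiolase gene acat2 from 24.7 ± 2 to 12.6 ± 2.18 CPM (-0.97 ± 0.15). At NF56 against NF50 this list had 2 rises and 1 fall, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0705). Of 45 oxidative phosphorylation genes, 9 fell and 2 rose, or 21 and 2 adjusted over the list alone (median -0.24; camera adjusted p = 3.8e-09; adjusted p = 0.17 with an estimated correlation). The gene cycs fell to 46.6 ± 3.01 CPM (-0.54 ± 0.09).

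The Polycomb cofactor gene jarid2 rose from 482 ± 17.9 to 1390 ± 302 CPM (1.53 ± 0.14, adjusted p = 0.00097), and jhdm1d, which codes for a histone lysine demethylase, rose from 101 ± 32.3 to 433 ± 113 CPM (2.09 ± 0.23, adjusted p = 0.0032). The Polycomb methyltransferase gene ezh2 fell from 25.4 ± 1.99 to 16 ± 1.6 CPM (-0.67 ± 0.10). Of the 33 genes of that list, 1 rose and 3 fell, or 1 and 6 adjusted over the list alone (camera adjusted p = 0.149). The gene dnmt3a fell to 675 ± 42.1 CPM (-0.32 ± 0.06, adjusted p = 0.019), a call lost without NF62 replicate 1, NF62 replicate 3 or NF66 replicate 2 (-0.38 to -0.29). The values of dnmt1 (46 ± 2.04 CPM, 0.10 ± 0.07), uhrf1 (7.77 ± 1.3 CPM, 0.05 ± 0.15), tet2 (71.5 ± 3.51 CPM, -0.18 ± 0.06), gadd45g (15.9 ± 3.5 CPM, -0.44 ± 0.16) and the merged pcna/figla model (31 ± 2.53 CPM, -0.14 ± 0.08) did not pass. The DNA methylation list had 3 falls and 0 rises among 20, or 4 falls adjusted over the list alone (camera adjusted p = 0.0583).

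Of 33 genes of neurogenesis and immature neurons, 3 fell and 0 rose, or 4 fell adjusted over the list alone (median -0.11; camera adjusted p = 0.000121; adjusted p = 0.127 with an estimated correlation). Among them was the tubulin gene tubb2b (1050 ± 73.1 to 590 ± 69 CPM, -0.83 ± 0.10). The median of that list was -0.25 to -0.08 with 1 library left out. Of 67 replication and cell division genes, 5 fell and 0 rose, or 9 fell adjusted over the list alone (median -0.09; camera adjusted p = 0.000625; adjusted p = 0.113 with an estimated correlation). Among these was the spindle checkpoint gene mad2l1 (-1.82 ± 0.30), a call lost without NF62 replicate 3 or NF66 replicate 2 (-1.99 to -1.65). The radial glia gene fabp7 fell from 124 ± 3.24 to 62.9 ± 5.05 CPM (-0.98 ± 0.06, adjusted p = 9.7e-05), the only call among 30 progenitor and radial glia genes, also adjusted over the list alone. That list (camera adjusted p = 0.0233; adjusted p = 0.271 with an estimated correlation) was not called without NF62 replicate 1, NF62 replicate 2 or NF66 replicate 2, where its adjusted p reached 0.185. Of 22 apoptosis genes, 4 fell and 0 rose, also adjusted over the list alone (median -0.18, camera adjusted p = 0.00463, and 0.113 with an estimated correlation). With 1 library left out the apoptosis median was -0.194 to -0.086. Of 29 heat shock and unfolded protein response genes, 2 fell and 0 rose, or 8 and 3 adjusted over the list alone (median -0.17; camera adjusted p = 0.00246; adjusted p = 0.241 with an estimated correlation). Of 17 choroid plexus and ependyma genes, 1 fell and 0 rose, or 3 and 1 adjusted over the list alone (median -0.19, camera adjusted p = 0.0129, and 0.172 with an estimated correlation), and otx2 fell (-0.44 ± 0.08), a call lost without NF62 replicate 3 or NF66 replicate 2 (-0.50 to -0.38). The choroid plexus median was -0.382 to -0.1 with 1 library left out. This list was not called with the replicate number as a block (camera adjusted p = 0.0607) or with the within-stage axis as a covariate.

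Of 30 neuropeptide and transmitter genes, 4 rose and 0 fell, or 7 rose adjusted over the list alone (median 0.22; camera adjusted p = 0.00135; adjusted p = 0.171 with an estimated correlation). The gene npy rose from 407 ± 36 to 524 ± 21.4 CPM (0.37 ± 0.07), a call lost without NF50 replicate 1, NF62 replicate 2 or 3, or NF66 replicate 2 or 3 (0.31 to 0.44). The thyrotropin-releasing hormone gene trh rose from 152 ± 14.5 to 198 ± 15.1 CPM (0.39 ± 0.09), a call lost in 11 of the 12 fits with 1 library left out (0.32 to 0.46). Synapse genes (1 of 55 higher, 0 lower, and 0 either way adjusted over the list alone by edgeR) were not called (camera adjusted p = 0.423). Myelin genes (2 of 24 higher, 0 lower, also adjusted over the list alone) were not called either (camera adjusted p = 0.124); mbp rose to 1090 ± 127 CPM (0.38 ± 0.08), a call lost in 11 of the 12 such fits (0.28 to 0.43). Of 70 ribosomal protein genes, 0 passed in either direction by edgeR, also adjusted over the list alone (median 0.06; camera adjusted p = 0.247). The pomc level was 35.9 ± 18.1 CPM (-0.59 ± 0.31, adjusted p = 0.39).

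Among genes with a symbol, libraries that did not overlap and at least 5 CPM in the higher group, the largest falls after thibz were those of gh1 (15.8 ± 5.49 to 4.88 ± 0.802 CPM, -1.68 ± 0.29), the threonine dehydrogenase gene tdh (-1.27 ± 0.22), the amino acid transporter gene slc7a10 (-1.25 ± 0.23) and mmp11. After jhdm1d and jarid2, the largest rises within those limits were those of cyp4f2 (1.19 ± 0.18), the complement gene cfb (5.5 ± 0.701 to 12.5 ± 2.5 CPM, 1.19 ± 0.17) and adap2 (1.13 ± 0.25). With 1 library left out, calls were lost for gh1 (NF62 replicate 3, NF66 replicates 1 and 2; -1.84 to -1.37), tdh (NF62 replicates 1 and 3, NF66 replicate 2; -1.42 to -1.18) and slc7a10 (NF62 replicate 3, NF66 replicate 2; -1.43 to -1.10). They were also lost for cyp4f2 (NF62 replicate 3, adjusted p = 0.0505) and, in 8 of the 12 fits, adap2 (0.89 to 1.36).

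Further list members fell at NF66 with calls that were lost in 2 to 10 of the 12 fits with 1 library left out, in every case including the fit without NF66 replicate 2. These were the mitotic kinase gene cdk1 (-1.75 ± 0.38; -2.81 without NF66 replicate 3), adamts3 (-0.86 ± 0.18), the merged model col1a1/myl4 (-0.77 ± 0.14), the merged model sox4/u4 (-0.63 ± 0.11), bmf (-0.61 ± 0.12), idh1 (-0.54 ± 0.12), the collagen gene col1a2 (-0.44 ± 0.08), the merged model odc1/pdia6 (-0.37 ± 0.06) and the chaperonin gene hspd1 (-0.31 ± 0.06). Of 27 vascular and meningeal genes, 1 rose and 2 fell, or 2 and 5 adjusted over the list alone (camera adjusted p = 0.0908). Of 30 extracellular matrix proteases and inhibitors, 1 rose and 4 fell, or 2 and 4 adjusted over the list alone (camera adjusted p = 0.131).

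The comparison of NF66 with NF50 spans metamorphosis as a whole. At NF66, 3507 genes were higher and 3689 lower than at NF50 (36.7% of those tested), 745 and 1193 of them by at least 2-fold; by limma on log2(TPM + 1), 3597 were higher and 969 lower. On that unscaled measure the median of all genes was 0.29 in place of 0.021, and the list medians of oxidative phosphorylation (0.06 in place of -0.27), DNA methylation (0.08 in place of -0.22) and apoptosis (0.08 in place of -0.22) changed sign. Large named rises, apart from tmed2, were those of thibz (3.78 ± 0.47), dio3 (3.73 ± 0.18) and klf9 (3.40 ± 0.34). Among genes with a symbol, libraries that did not overlap and at least 5 CPM at NF50, the largest falls were those of pla2g2e (-6.94 ± 0.40), crisp1.7 (-6.89 ± 0.52), the mitotic kinase gene cdk1 (-5.28 ± 0.37), eda2r (-5.25 ± 0.58) and mad2l1 (-5.03 ± 0.28). Without NF66 replicate 3 the value of cdk1 was -6.33, and without NF50 replicate 3 that of eda2r was -4.49 and that of thibz 3.18. The model that carries the name tmed2 had 0 counts at NF50 and 1102 over the NF66 libraries (19.53, 10.8 and 14.68 CPM). That is at least 334-fold higher against a floor of 3 counts over the group, and the floor covers counting error only. Libraries of NF56 also differed widely (12.42, 3.06 and 0 CPM). Whether this model covers the main locus of the gene was not analysed here, so its level is not read as that of the gene. The receptor gene thrb rose (2.35 ± 0.15), as did mbp (1.07 ± 0.08) and dnmt3a (0.87 ± 0.06). Falls were called for uhrf1 (-2.43 ± 0.15), the merged pcna/figla model (-1.51 ± 0.08), pomc (-1.24 ± 0.31), gadd45g (-1.18 ± 0.16) and dnmt1 (-0.54 ± 0.07). Of 16 pituitary genes 3 rose and 6 fell, or 4 and 6 adjusted over the list alone, and that list was not called (camera adjusted p = 0.549). The values of the thra model (0.22 ± 0.39) and tet2 (-0.10 ± 0.06) did not pass.

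Over the same span 60 of 67 replication and cell division genes fell and 3 rose, or 61 and 3 adjusted over the list alone (median -1.94; camera adjusted p = 4.37e-28, and 0.000972 with an estimated correlation). Of 30 progenitor and radial glia genes 21 fell and 0 rose, or 24 fell adjusted over the list alone (median -0.81; camera adjusted p = 9.64e-11, and 0.0318 with an estimated correlation). Of 55 synapse genes 32 rose and 1 fell, or 33 and 1 adjusted over the list alone (median 0.45; camera adjusted p = 6.78e-09, and 0.0243 with an estimated correlation). All 70 ribosomal protein genes fell, also adjusted over the list alone (median -1.26; camera adjusted p = 7.54e-28; adjusted p = 0.256 with an estimated correlation). Of 33 immature neuron genes 21 fell and 4 rose, also adjusted over the list alone (median -0.72; camera adjusted p = 4.31e-06; adjusted p = 0.113 with an estimated correlation). Of 24 myelin genes 12 rose and 5 fell, also adjusted over the list alone (median 0.54; camera adjusted p = 0.0296; adjusted p = 0.337 with an estimated correlation). Of 20 DNA methylation genes 10 fell and 2 rose, also adjusted over the list alone (median -0.22; camera adjusted p = 0.0163; adjusted p = 0.113 with an estimated correlation). The 17 thyroid hormone response genes had 6 rises and 4 falls, also adjusted over the list alone (camera adjusted p = 0.128). Of 22 apoptosis genes 7 fell and 1 rose, also adjusted over the list alone (camera adjusted p = 0.0342, and 0.181 with an estimated correlation), a call lost without NF66 replicate 2 (adjusted p = 0.0634). That call was also lost by DESeq2, with the stricter filter, with the replicate number as a block and by limma on log2(TPM + 1).

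A further 6 called lists of that comparison did not hold with an estimated correlation. Of 45 oxidative phosphorylation genes 26 fell and 1 rose, or 28 and 1 adjusted over the list alone (median -0.27; camera adjusted p = 1.03e-06; adjusted p = 0.228 with an estimated correlation). Of 18 cholesterol synthesis genes 10 fell and 0 rose, also adjusted over the list alone (median -0.38; camera adjusted p = 0.00246; adjusted p = 0.387 with an estimated correlation). Of 27 vascular and meningeal genes 14 fell and 4 rose, or 16 and 4 adjusted over the list alone (median -0.51; camera adjusted p = 0.00273; adjusted p = 0.127 with an estimated correlation); the list was not called by DESeq2. Of 17 choroid plexus and ependyma genes 8 fell and 0 rose, or 9 fell adjusted over the list alone (median -0.47; camera adjusted p = 0.00408; adjusted p = 0.127 with an estimated correlation). Of 12 red blood cell genes 6 fell and 0 rose, also adjusted over the list alone (median -0.70; camera adjusted p = 0.00416; adjusted p = 0.127 with an estimated correlation). Of 30 hypothalamic neuropeptide and transmitter genes 15 rose and 3 fell, or 16 and 5 adjusted over the list alone (median 0.38; camera adjusted p = 0.0129; adjusted p = 0.251 with an estimated correlation).

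**Figure D3:**
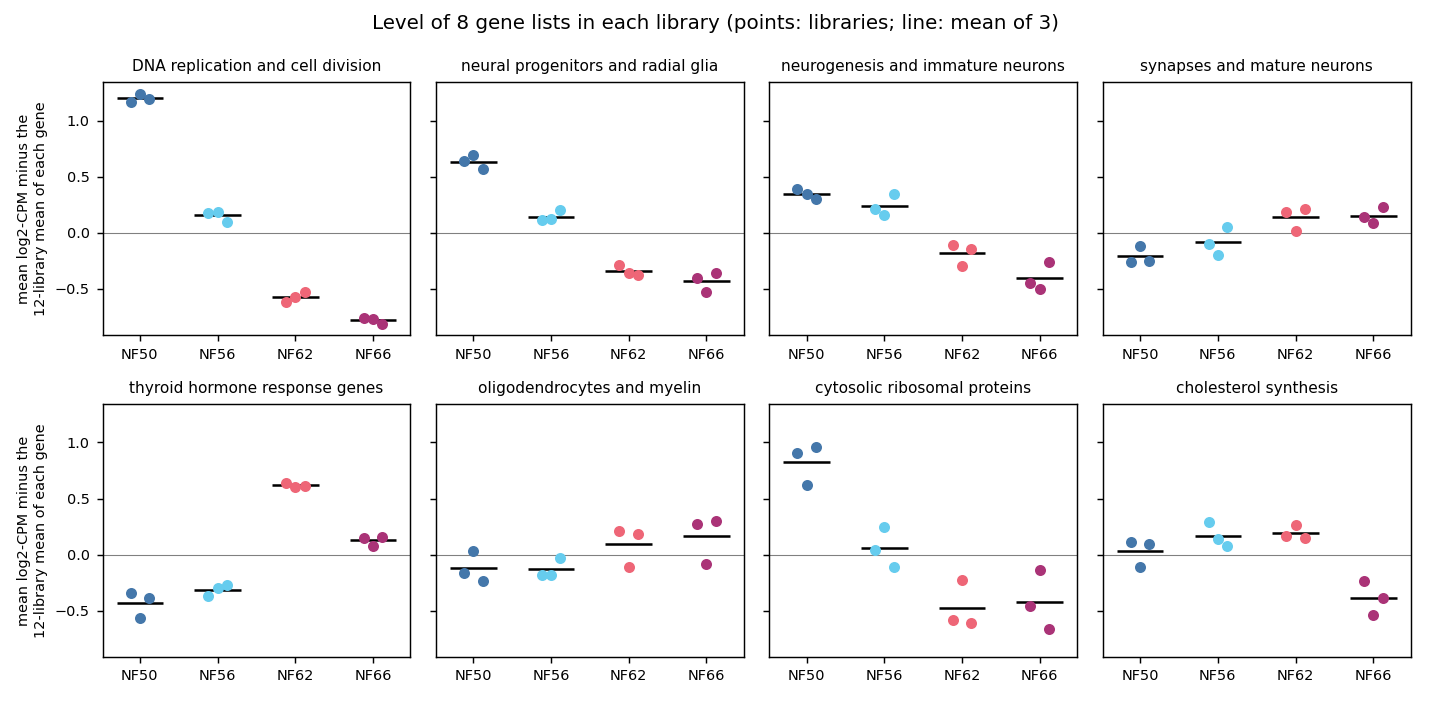
Mean log2 level of 8 gene lists in each of the 12 libraries by stage. Replication and ribosomal protein genes step down from NF50 to NF62, with median log2 fold changes of -1.07 and -0.79 at NF56 and -0.54 and -0.53 at NF62.

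To ask which genes stood apart at the climax, NF62 was compared with the mean of NF56 and NF66. At NF62, 865 genes were higher and 647 lower (7.7% of those tested), 42 and 44 of them by at least 2-fold. Higher and lower genes numbered 23 and 23 by limma on log2(TPM + 1), 1302 and 978 by DESeq2, and 553 and 423 with only the libraries of the 3 stages in the fit. Without NF62 replicates 1, 2 and 3 in turn, 336, 461 and 419 were higher, and without NF56 replicate 2, 551 were. The lower genes numbered 208 and 226 without NF62 replicate 1 and 3, and 420 and 374 without NF56 replicate 1 and 2. Among genes with a symbol, libraries that did not overlap and at least 5 CPM in the higher group, the largest rises were those of thibz (4.47 ± 0.31), dio3 (2.41 ± 0.13), inhbb (1.81 ± 0.23), fam83g (1.42 ± 0.14) and nudt22 (1.37 ± 0.05, adjusted p = 1.6e-07). The level of nudt22, which codes for a nucleotide sugar hydrolase, was 101 ± 6.14, 317 ± 10.7 and 148 ± 4.98 CPM at NF56, NF62 and NF66. The largest falls within those limits were those of jhdm1d (-1.87 ± 0.21), c5orf41 (-1.30 ± 0.32), jarid2 (-1.28 ± 0.13), slc12a8 (-1.24 ± 0.22) and the lipid amidase gene naaa (-1.07 ± 0.19). The call of c5orf41 was lost without NF50 replicate 1 or any of the 3 NF62 libraries (-1.53 to -1.09), and that of slc12a8 without NF62 replicate 1 (adjusted p = 0.0522).

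Some genes changed on the way into the climax and changed back on the way out. In the same pair of comparisons, 123 genes rose and then fell, among them thibz, inhbb, fam83g and nudt22, and 103 fell and then rose, among them jarid2, jhdm1d, cfb and naaa. These counts depended on the fit: they were 2 and 0 with only the libraries of the stages compared, 2 and 1 by limma on log2(TPM + 1), and 276 and 215 by DESeq2. Independent lists of those sizes would share 34.8 and 24.2 genes. The comparisons share the NF62 libraries, so noise in these moves a gene's fold changes in opposite directions. In 20 simulations with that sharing and no true change, 0 genes were of either kind. The simulations drew each gene independently, so they hold no within-stage axis like that of the libraries. Almost no gene is called in such simulations, so they leave open what shared noise adds among called genes. The covariance of the fold changes over all genes was -0.0331, against -0.0569 (-0.0628 to -0.0505) in the simulations. True changes that go the same way at both steps also raise it, so it does not tell how much shared noise added. In addition, 33 genes rose at both steps and 61 fell at both, against 26.8 and 31.4 for independent lists. Counts of rise-and-fall and fall-and-rise genes moved with single libraries. They were 29 and 13 without NF62 replicate 3, 36 and 29 without NF62 replicate 1, 32 and 37 without NF66 replicate 2, and 47 and 69 without NF62 replicate 2. They were 67 and 62 without NF50 replicate 1, 68 and 80 without NF50 replicate 4, 74 and 61 without NF56 replicate 1, and 63 and 54 without NF56 replicate 2. Without NF66 replicate 1 they were 69 and 62, and without NF66 replicate 3 they were 77 and 109. A test for any difference among the 4 stages called 7763 genes (39.6% of those tested).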

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

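The within-stage axis as a covariate and the joint removal of NF56 replicate 3 and NF62 replicate 2 (the shallowest library and the library farthest along the within-stage axis removed) were chosen after seeing the data. None of the 171 called values of named genes changed sign, and none of the 47 called list tests its direction by camera or fry, under any alternative run for it; signs of other called genes were not analysed here, and the medians of 8 called list tests changed sign by limma on log2(TPM + 1). Counts of genes were within 1.5 times the reported ones with median-of-ratios factors, the stricter filter and effective lengths as offsets, and each of these kept all called named genes it tested (171, 170 and 171). Effective lengths differed by at most 0.01 between libraries, so that setting could hardly come out otherwise. The leading component held 35.4% of the variance with a prior count of 0.5 and 42.6% over the 500 most variable genes. Counts below are given as higher and lower genes; where no cause is named, the cause was not tested.

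DESeq2 gave 623 and 743 genes for NF66 against NF62, 1302 and 978 for NF62 against the mean of NF56 and NF66, and 276 genes that rose and fell and 215 that fell and rose. With no low-count filter these were 175 and 188, 428 lower at the climax, and 61 that rose and fell. Against a minimum fold change of 1.5, a stricter question by construction, the counts were 25 and 153 for NF56 against NF50, 108 and 145 for NF62 against NF56, 2 and 4 for NF66 against NF62, 670 and 1070 for NF66 against NF50, 17 and 7 at the climax, 2 and 1 for the reversing genes, and 65 named genes. By limma on log2(TPM + 1), whose medians were shifted by 0.32 at NF56 and 0.29 at NF66 against NF50, they were 333 and 122, 173 and 274, 1 and 2, 969 lower at NF66 than at NF50, 23 and 23 at the climax, 3381 for any stage, 2 and 1 for the reversing genes, and 75 named genes. With only the libraries of the stages compared, which leaves fewer residual degrees of freedom, edgeR gave 0 and 4 for NF66 against NF62 (2415 at an unadjusted p below 0.05), 553 and 423 at the climax, and 2 and 0 reversing genes. The within-stage axis as a covariate gave 3703 and 3854, 3716 and 3563, 1694 and 1712 for the successive pairs, 5409 higher at NF66 than at NF50, 2474 and 2175 at the climax, 13058 for any stage, and 675 and 636 reversing genes; the axis was estimated from the same residuals, so these counts are too high by construction. The joint removal gave 148 and 151 for NF66 against NF62, 376 and 403 at the climax, and 42 and 65 reversing genes. Of the 47 called list tests, camera with an estimated correlation called 9. Of all 104 list tests, fry called 71, with 46 of the 47 among them.

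The replicate number as a block gave 2554 and 2889, 3033 and 2868, and 1008 and 1004 for the successive pairs, 1754 and 1493 at the climax, and 381 and 397 reversing genes. Number 4 occurs only at NF50, so its block term fits NF50 replicate 4 alone. With the block the NF50 level therefore rests on replicates 1 and 3. The pairing check compared the residuals of libraries with the same number at different stages: correlations were 0.52 to 0.64 for number 2 and 0.45 to 0.59 for number 3, but -0.18 to 0.09 for number 1. Number 1 lay near the middle of the within-stage axis at NF50, NF56 and NF66 (-9, -8.7 and -7.7). The low correlations among those libraries (0.03 to 0.09) therefore do not speak against a batch. At NF62, however, number 1 lay at 25, near replicate 3 of that stage (29.1). It correlated at -0.14, -0.15 and -0.18 with number 1 at NF50, NF56 and NF66. That library thus did not follow its number, which goes against a batch shared by all libraries numbered 1. The design names no pairs, so the numbers were not taken as pairs. The within-stage axis nevertheless followed the numbers 2 and 3: replicate 3 was the highest of its stage at every stage (32.9, 42.1, 29.1 and 49.8) and replicate 2 the lowest at the 3 stages that have it (-33.4, -54.2 and -42.2). As a hint from the data, not the design, the library of the same number was the best correlated of another stage in 6 of 6 checks for number 2, 11 of 12 for number 3 and 0 of 12 for number 1. Under the block 4 called lists were not called: choroid plexus and ependyma at NF56 against NF50 (camera adjusted p = 0.0656) and at NF66 against NF62 (0.0607), thyroid hormone signalling machinery at NF62 against NF56 (0.0522), and apoptosis at NF66 against NF50 (0.0566).

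With 1 library left out in turn, counts ranged from 641 to 1377 higher and 893 to 1683 lower for NF56 against NF50, 1343 to 2056 and 1108 to 1855 for NF62 against NF56, 38 to 261 and 75 to 310 for NF66 against NF62, 2819 to 3664 and 3074 to 3823 for NF66 against NF50, and 336 to 825 and 208 to 688 at the climax. For any stage they ranged from 6331 to 7969, for genes that rose and fell from 29 to 113, for genes that fell and rose from 13 to 109, for called lists from 46 to 52, and for called named genes from 137 to 166. Not run were the minimum fold change for the gene lists and for the test of any stage, and the fit to only the libraries of the stages compared for the test of any stage, where it does not apply. Depth limits what can be said of genes below about 1 CPM, such as the thra model, and NF56 replicate 3, at 12046529 counts, sets the lowest depth.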

Other observations

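The test of gene length and 6 gene lists (telencephalon; hindbrain and spinal cord; midbrain and cerebellum; hypothalamus, preoptic area and thalamus; antigen presentation and interferon response; amino acid starvation response) were chosen after the results were seen; the genes named from them were chosen after their values were seen. Over 24 tests of these lists, the amino acid starvation response fell at NF56 against NF50, with 22 of 31 genes lower and 0 higher (median log2 fold change -0.87; camera adjusted p = 9.32e-13; adjusted p = 0.303 with an estimated correlation). Among them psph (-1.89 ± 0.27), atf5.2 (-1.94 ± 0.23), psat1 (-1.41 ± 0.20) and slc7a3 (-1.78 ± 0.25) fell. For asns and psat1, NF50 replicate 3 held the highest level: asns was at 42.02, 79.55 and 29.33 CPM in NF50 replicates 1, 3 and 4, and psat1 at 233.95, 303.9 and 151.07 CPM. Against NF50, 26 of the 31 were lower at NF66 (median -1.0; camera adjusted p = 2.57e-09; adjusted p = 0.37 with an estimated correlation). Genes of antigen presentation had 3 rises and 1 fall among 27 at NF56 (median 0.67; camera adjusted p = 0.00223; adjusted p = 0.555 with an estimated correlation). At NF62 tapbp stood at 10.18, 64.85 and 12.92 CPM and ifi35 at 5.7, 27.51 and 6.72 CPM, both highest in replicate 2.

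Hindbrain and spinal cord genes fell at NF62 against NF56, with 5 of 14 lower and 0 higher (median -1.37; camera adjusted p = 0.000138; adjusted p = 0.296 with an estimated correlation), among them hoxa3 (-0.86 ± 0.20) and mafb (-0.41 ± 0.10). Midbrain and cerebellum genes had 5 falls and 1 rise among 9 (median -0.52; camera adjusted p = 0.00223; adjusted p = 0.37 with an estimated correlation). Telencephalic genes had 5 rises and 2 falls among 15 (median 0.48; camera adjusted p = 0.057), and genes of the hypothalamus, preoptic area and thalamus 4 falls and 0 rises among 19 (median -0.22; camera adjusted p = 0.128). At NF66 against NF62 the lists of the hindbrain (median -0.79; camera adjusted p = 0.0025), the midbrain (-0.14; 0.0235) and the hypothalamus, preoptic area and thalamus (-0.18; 0.0235) were called lower, with 1, 0 and 0 genes lower by edgeR, and with an estimated correlation the adjusted p were 0.303, 0.468 and 0.303. At NF66 against NF50 the hindbrain (median -2.18; camera adjusted p = 0.000128) and midbrain lists (-0.78; 0.0108) were called lower, with adjusted p = 0.296 and 0.437 with an estimated correlation. Whether the stages differed in how much neighbouring brain tissue was taken along was not tested. It therefore stays open for the comparisons of stages, and the test of region markers below covers only the spread within stages. Among genes that fell into the climax and rose after it, also chosen after their values were seen, were the peptide gene pth2 (15.1, 6.87 and 12.4 CPM at NF56, NF62 and NF66), the kinase gene vrk3 (35.6, 18.8 and 32 CPM), cby1 (89.5, 60.7 and 113 CPM) and the olfactomedin-domain gene myoc (4.1, 1.12 and 2.33 CPM).

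Libraries of a stage spread along an axis that held 54.2% of the variance within stages. Depth is argued against: with every library thinned to 12046529 counts the axis still held 50.4%. Gene length and expression level together explained 7.6% of the variance of the loadings, which argues against a length bias. Brain regions taken along are argued against as well, since the axis explained a median 0.19 of the within-stage variance of 57 region markers, against 0.45 (0.28 to 0.61) in 1000 random lists matched on expression. Positions on the axis followed the replicate numbers 2 (lowest of its stage) and 3 (highest of its stage), so a batch or day behind those numbers remains open with RNA quality and dissection time; no biological explanation was tested, since the labels name none within a stage.

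Ribosomal protein genes took 9.76 ± 0.82, 6.15 ± 0.61, 4.22 ± 0.44 and 4.39 ± 0.64% of the counts at NF50, NF56, NF62 and NF66 (n = 3 each), and they followed the within-stage axis with a median correlation of -0.96. The shift of all other genes along that axis from NF50 to NF66 predicted a change of -0.1 against the -1.26 measured, which argues against the axis as the cause of most of the fall. Other genes matched on length and expression changed by 0.18 (0.01 to 0.36), which argues against a bias toward short and abundant models. Scaling on the other genes alone gave a median of -1.26 again but moved the other genes by only -0.004 at the median, so that test could not come out otherwise and their own share of the counts stays open. Whether cell composition or expression per cell changed between the stages stays open as well.

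Other splits of the libraries were refitted in the same way. The stage differences stay in the regrouped libraries. They widen the spread within groups, which lowers gene counts, and can leave groups unlike in lists of genes that move together. For the comparisons of 3 libraries with 3 the 10 splits are too few for a share under 0.05. The real split called 2834 genes between NF50 and NF56, 3704 between NF56 and NF62 and 7196 between NF50 and NF66, each as 1 of the 10 with a highest other count of 0. Between NF62 and NF66 the real split called 620, and 2 of the 10 splits called as many; the highest other called 2165. That split set NF62 replicates 1 and 3 with NF66 replicate 3 against NF62 replicate 2 with NF66 replicates 1 and 2, which follows the within-stage axis and points to a structure of the libraries. For NF62 against the mean of NF56 and NF66, 2 of 100 splits called as many as the real 1512; the other called 3773, more than the real split, which again points to structure, although the share was under 0.05. Of 100 splits of the 12 libraries, 1, the real one, called as many genes that differ between any stages (7763, with a highest other of 2474). It was also the only 1 of the 100 that called as many gene lists (47, with a highest other of 45). Among the splits drawn the gene count stood well apart from the others, although mixing the stages within groups lowers the other counts. The list count did not, so it does not tell the stages from other groupings. The other 99 splits called 11 to 45 of the 104 list tests, with a median of 28, although 96 of them called 0 genes. Stage differences remain in those splits, so the median is not a rate in the absence of differences. A list called with the preset correlation alone is nevertheless not by that call tied to the stages. As many genes that change at NF62 and change back (226; highest other 0) were also called by 1 of the 100, but a split that called 0 genes at any stage, as most others did, had no gene that could reverse, so this says nothing further about reversal.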
